A study of Mus musculus with 13 samples.

How the data were processed

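Gene expression was measured in endometrium from 13 ovariectomized C57BL/6 mice after 12 weeks of treatment. The mice formed 4 groups: normal chow without a pellet (CON, n = 3), a subcutaneous pellet that releases 17-β estradiol on chow (E2, n = 4), a high-fat diet without a pellet (HD, n = 3) and the pellet with the high-fat diet (MIX, n = 3). Each mouse gave 1 sample and 1 array. Biotinylated cDNA was prepared from 250 ng of total RNA with the Affymetrix WT PLUS kit, per the labels' protocols.

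The deposited values are log2 expression values per array feature (a transcript cluster), made by the authors with RMA per the submitters' processing notes. RMA corrects each array for background, equalises the distributions of the arrays and summarises the probes of a feature. Its version, the array library behind the features and any filtering are not given in the sources used here. RMA is run over all arrays together, so the values of a mouse depend on the other arrays, and small differences of dim features are compressed. Values ran from 1.66 to 13.8, and array medians lay between 4.48 and 4.71. Pearson correlations between arrays across features were 0.960 to 0.995 over 78 pairs. At most 2742 of 65929 features had an identical value in any pair of arrays, so no array was a copy of another. An array gives no read depth, and the number of mice per group limits the precision.

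Features were named through the annotation table supplied for this array, with 827 symbols updated through their Entrez identifiers. Of 65929 features, 30604 carried 1 gene symbol, 2146 carried several and 33179 were unnamed here. For gene lists and named genes, each symbol was represented by the feature with the highest mean over all mice. All 65929 features entered the tests.

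Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 13 mice in 1 fit of 4 group coefficients. The sample titles carry 2 styles of animal code, a numbered style (2 CON, 3 E2 and 2 HD mice) and a lettered style (1 CON, 1 E2, 1 HD and all 3 MIX mice). What the styles stand for is not given in the sources used here. Code style was a covariate in the fit, because a difference between the styles would otherwise fall on MIX. It is estimated from CON, E2 and HD, where the lettered style has 1 mouse per group, and 0 features differed by code style at an adjusted p under 0.05 in limma, with 3516 at an unadjusted p under 0.05 where chance gives 3296. The fit had 8 residual degrees of freedom and a prior of 2.225. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all features of a comparison, two-sided, with no minimum fold change.

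The comparisons were E2 with CON, HD with CON, MIX with CON, MIX with E2, MIX with HD, and the interaction, which is the pellet difference on the high-fat diet minus that on chow. The comparisons, the fit with its covariate, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the named genes are the 10 with the largest positive and the 10 with the largest negative differences among features with 1 symbol that passed and had no overlap between the groups. Where fewer than 10 qualified, the 10 with the smallest unadjusted p are given as values. Genes with predicted or clone-based symbols (Gm numbers, Rik and LOC) and olfactory and vomeronasal receptor genes (Olfr and Vmn) were left out of both rankings. Statements on the genes with the smallest p refer to the remaining genes with 1 symbol. From each list described, up to 4 passing members, or else up to 2 with the smallest p, are given. The rule also names Esr1, Pgr, Ltf, Lcn2 and C3 in every comparison as a check of the estradiol labels. The first 4 are given below for E2 with CON, HD with CON and the averaged pellet difference only, and C3 had no feature with 1 symbol.

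Gene lists covered uterine hormone responses, metabolism, inflammation, stress and markers of cell types that scraped endometrium can hold. The 41 lists had 1133 memberships, of which 980 matched a feature with 1 symbol. Lists with fewer than 5 measured members were not tested, which left out the blood markers, so 40 lists were tested. Lists were tested with camera of limma at its preset correlation of 0.01 between genes, two-sided, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. Members that passed were counted over all features and adjusted over the list alone.

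Further tests were added after the planned comparisons had given few passing features and after the camera calls had been lost with an estimated correlation. They are the pellet difference averaged over both diets, the diet difference averaged over both pellet states, and a test with the mouse as the unit. In the last, a list's score is the mean log2 value of its members in a mouse, and the difference in scores was tested with an exact two-sided permutation test over all 700 relabelings of the mice within diets (for the pellet) or within pellet states (for the diet), adjusted over the 40 lists. The same relabelings within code style, the results without E2 replicate 1 and MIX replicate 3, and list scores and camera calls without each mouse in turn were also added then.

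The fits were tested on simulated data with independent features that had the means and residual spreads of the real ones, 200 of which were given known differences. The alternatives that were tried are no code style term, code style as a random block, a block by replicate number, only the groups compared, only mice of 1 code style, quantile normalization again, median centring, leaving out dim features, features with 1 symbol only, the trend and robust options, array weights, a minimum absolute log2 difference of 1, and leaving out each mouse in turn. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No sample and no feature was left out.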

Results

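The series asks how estradiol and a high-fat diet, alone and together, alter the endometrial transcriptome once the ovaries have been removed. Expression of 65929 array features was measured in the endometrium of 13 mice: 3 on chow (CON), 4 on chow with an estradiol pellet (E2), 3 on a high-fat diet (HD) and 3 with both (MIX). Values are log2 expression, differences are log2 differences with their standard error (SE) from limma, and group values are means ± SD over the mice. The first principal component held 33.4% of the variance, and MIX replicate 3 (score 102.5) and E2 replicate 1 (46.99) lay farthest along it. On the second (15.2%) MIX replicate 2 stood apart, at -72.19 where the next mouse had -20.12, and it had the highest stromal (9.149), endothelial (6.937) and smooth muscle (6.935) marker scores of all mice. Trp63 in CON, E2 and HD, Akr1c21 in the same groups, S100a8 in CON and HD and Bmp5 in MIX averaged below the median of the arrays, near background. Differences given for these genes may therefore be compressed by an unknown amount, and the fitted ones also depend on the code style term. All 3 MIX mice carry lettered codes in their titles, so each limma or camera difference from MIX is adjusted for code style through 1 lettered mouse in each other group. Differences in list scores are plain differences of group means without that adjustment, so they can depart from the medians given beside them.

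The comparison of E2 with CON addresses what estradiol does on chow. The gene with the smallest p was Olfm4, which encodes a secreted glycoprotein of epithelia, at 8.30 ± 1.14 (SD, n = 4) in E2 and 4.94 ± 0.23 (SD, n = 3) in CON, a difference of 3.31 (SE 0.47, adjusted p = 1 in limma). Csf1, the growth factor of macrophages, differed by 1.27 (SE 0.24), the mucin Muc16 by 1.17 (SE 0.22), the small GTPase Rap2a by 0.43 (SE 0.08), the scaffold protein gene Tanc2 by 0.39 (SE 0.07) and the lysosomal membrane protein gene Scarb2 by 0.48 (SE 0.09). Differences were negative for Spry1, an inhibitor of growth factor signalling (-0.54, SE 0.10), the homeobox gene Barx2 (-0.60, SE 0.12), Vwa8 (-0.61, SE 0.11) and Zfp362 (-0.30, SE 0.06). None of these passed, and limma called 0 features, with 2651 at an unadjusted p under 0.05 where chance gives 3296. In simulated data of the same size and spread this comparison recovered 73% of 100 features given a log2 difference of 1 and 96% of 100 given 2. The changed features were drawn at random from all features, with independent noise. Such shares describe features of typical spread (median SE 0.109 here over genes with 1 symbol), not variable genes such as Olfm4. Here and below they do not show that little changed where 0 features were called.

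Genes that report on estradiol in the uterus also did not pass between E2 and CON. Ltf, which encodes lactoferrin, was at 12.2 ± 0.26 in CON and 12.6 ± 0.21 in E2 (difference 0.44, SE 0.24), and Lcn2, which encodes lipocalin 2, at 11.6 ± 0.33 and 11.8 ± 0.27 (0.17, SE 0.20). The progesterone receptor gene Pgr was at 10.5 ± 0.34 and 9.96 ± 0.52 (-0.57, SE 0.40), and the estrogen receptor gene Esr1 at 9.44 ± 0.24 and 8.96 ± 0.23 (-0.46, SE 0.24). Ltf and Lcn2 were thus among the bright features of the arrays in mice without a pellet as well.

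By camera, 17 of 40 lists were called between E2 and CON. Macrophage markers had a median difference of 1.25, with 30 of 32 members higher (adjusted p = 1.55e-20, and adjusted p = 0.364 with an estimated correlation). The members past the threshold, 17 adjusted over the list alone and 0 over all features, included Csf1r, Adgre1, Cd68 and Itgax. Interferon-stimulated genes had a median of 0.92 and 30 of 30 members higher, among them Gbp2 (1.78, SE 0.50) and Gbp3 (1.45, SE 0.41; adjusted p = 9.29e-20, and adjusted p = 0.374 with an estimated correlation). Their mean score differed by 0.916 per mouse (exact p = 0.114), and by 0.506 without E2 replicate 4. Cytokine and chemokine genes had a median of 0.80, with Csf1 and Il1b (4.07, SE 1.11) as examples (adjusted p = 3.55e-15, and adjusted p = 0.364 with an estimated correlation). Mesothelial markers had a median of 0.80 with 8 members past the threshold adjusted over the list alone and 0 over all features (adjusted p = 3.11e-11, and adjusted p = 0.364 with an estimated correlation). The list of uterine estradiol targets had a smaller median of 0.20, with 25 of 37 members higher, Olfm4 and Sprr2d (2.66, SE 0.90) foremost (adjusted p = 0.000841, and adjusted p = 0.532 with an estimated correlation), and a score difference of 0.437 that was 0.264 without CON replicate 3. The other called lists, like all 17, were lost with an estimated correlation. They were complement and mucosal defence, antigen presentation, matrix, protein folding stress, respiratory chain, hypoxia and glycolysis, cholesterol efflux, squamous, granulocyte and lymphocyte genes, all higher, and smooth muscle and adipocyte markers, both lower. Several rested on single mice: without CON replicate 3 the score difference went from -0.107 to 0.038 for adipocyte, -0.142 to -0.024 for smooth muscle, 0.392 to 0.234 for antigen presentation, 0.346 to 0.165 for matrix and 0.11 to 0.068 for respiratory chain genes. Without E2 replicate 1 it was 0.037 for respiratory chain genes and 0.265, from 0.428, for squamous markers. Adipocyte markers had -0.192 without CON replicate 1, -0.165 without CON replicate 2 and -0.051 without E2 replicate 4, and smooth muscle markers -0.277 without CON replicate 1 and -0.082 without E2 replicate 3. Another split of the same 7 mice gave 19 called lists.

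The comparison of HD with CON addresses the high-fat diet without estradiol. Its smallest p belonged to Ccnd2, which encodes cyclin D2, at 7.13 ± 0.61 in HD and 9.13 ± 0.20 in CON (-2.0, SE 0.37). Slc9a9, a sodium and proton exchanger of endosomes, differed by 0.92 (SE 0.21) and Scarb2 by 0.44 (SE 0.09), while Actn1 (-0.58, SE 0.11), Cbll1 (-0.58, SE 0.11), Reep6 (-0.68, SE 0.15), Klf10 (-0.63, SE 0.15), Ephx1 (-0.71, SE 0.17), Rela (-0.46, SE 0.11) and Zfp362 (-0.31, SE 0.06) had negative differences. Every one of these had an adjusted p of 1, and limma called 0 features, with 1918 at an unadjusted p under 0.05. Ltf, Lcn2, Pgr and Esr1 differed by 0.47 (SE 0.25), 0.31 (SE 0.22), -0.61 (SE 0.43) and -0.23 (SE 0.26). Simulated data recovered 75% of 100 features given a log2 difference of 1 here and 95% of 100 given 2.

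No list of lipid genes was called between HD and CON: lipogenesis had a median of -0.08 (adjusted p = 0.0722), cholesterol synthesis -0.07 (adjusted p = 0.245) and fatty acid oxidation -0.01 (adjusted p = 0.859). Scd1, the desaturase that makes monounsaturated fatty acids, was at 7.49 in HD and 8.41 in CON (-0.92, SE 0.34), and the coactivator of mitochondrial genes Ppargc1a at 6.87 and 7.64 (-0.77, SE 0.36), neither passing. Camera called 8 of 40 lists. Replication and mitosis genes had a median of -0.36 with 35 of 37 members lower, Plk1 (-1.17, SE 0.72) and Ccnb2 (-1.27, SE 0.81) among them (adjusted p = 4.28e-05, and adjusted p = 0.819 with an estimated correlation). Their score difference of -0.475 (exact p = 0.5) hung on single mice: it was -0.078 without HD replicate 3, -0.235 without CON replicate 1, -0.721 without CON replicate 3 and -0.990 without HD replicate 1. Macrophage markers had a median of 0.50 with 30 of 32 members higher (adjusted p = 2.97e-08, and adjusted p = 0.819 with an estimated correlation). Mesothelial, complement, respiratory chain and glycolysis genes were called higher and heat shock and adipocyte genes lower, with adjusted p = 0.819 with an estimated correlation for each. Without CON replicate 3 the score difference went from -0.124 to 0.02 for adipocyte, 0.281 to 0.165 for glycolysis, 0.327 to 0.217 for complement and 0.107 to 0.064 for respiratory chain genes. Without HD replicate 3 it went from -0.192 to -0.084 for heat shock genes, to 0.181 for glycolysis and to -0.209 for adipocyte genes. Respiratory chain genes had 0.061 without HD replicate 2, and adipocyte genes -0.21 without CON replicate 1 and -0.069 without HD replicate 1.

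The comparison of MIX with CON addresses both treatments together, and it gave the first features past the threshold. Bmp5, which encodes a bone morphogenetic protein, fell from 5.93 ± 0.28 in CON to 4.31 ± 0.21 in MIX (adjusted difference -1.88, SE 0.18, adjusted p = 0.0268), below the array medians. Alas2, the first enzyme of heme synthesis in red cell precursors, rose from 7.17 ± 0.64 to 8.53 ± 0.22 (2.18, SE 0.18, adjusted p = 0.0139), and it followed the hemoglobin features over the 13 mice (Pearson's r = 0.931, permutation p = 1e-05). Without the code style term the Alas2 difference was 1.361. All 3 MIX mice lay beyond all 3 CON mice for both genes. Just short of the threshold, each at an adjusted p of 0.0532, were Olfm4 (5.29, SE 0.58, 39.0-fold), the basal keratin gene Krt15 (2.50, SE 0.31), Trp63, the transcription factor of basal epithelial cells (0.69, SE 0.08), Tanc2 (0.76, SE 0.09), Rap2a (0.81, SE 0.10), the hemoglobin pseudogene Hba-ps4 (1.66, SE 0.19), Cdh4, which encodes R-cadherin (-1.35, SE 0.16), and Hs3st3b1, a heparan sulfate sulfotransferase gene (-0.97, SE 0.12).

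Limma thus called 1 feature up and 1 down between MIX and CON, with 5498 at an unadjusted p under 0.05. No overlap between the 3 MIX and 3 CON mice was seen for 17.9% of features, where chance gives 10%. In simulated data 68% of 100 features given a log2 difference of 1 and 93% of 100 given 2 were recovered in this comparison. The count depended on single mice. It was 0 without CON replicate 1, 2 or 3, E2 replicate 1 or 2 or HD replicate 1, and 1 without E2 replicate 3 or HD replicate 2. It was 10 without E2 replicate 4, 12 without HD replicate 3, 40 without MIX replicate 1 and 89 without MIX replicate 2.

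Squamous epithelial markers stood out among the lists in MIX against CON, with a median of 0.85 and 27 of 28 members higher (adjusted p = 8e-17, and adjusted p = 0.314 with an estimated correlation). The members past the threshold, 14 adjusted over the list alone and 0 over all features, included Krt5, Krt13, Krt14, Krt15 and Trp63. Macrophage markers had a median of 1.37 with 17 members past the threshold adjusted over the list alone and 0 over all features (adjusted p = 7.28e-15, and adjusted p = 0.314 with an estimated correlation), and a score difference of 1.33 that was 0.852 without MIX replicate 3. Complement and mucosal defence genes had a median of 0.97, with C4b at 1.71 (SE 0.34; adjusted p = 2.09e-08, and adjusted p = 0.314 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.90, with Pkm at 0.99 (SE 0.23) and P4ha1 at 1.19 (SE 0.28; adjusted p = 4.58e-10, and adjusted p = 0.314 with an estimated correlation). Uterine estradiol targets had a median of 0.49 with 6 members past the threshold adjusted over the list alone, Olfm4, Agr2, Gja1, Clca3a1, Sprr2b and Sprr2d, and 0 over all features (adjusted p = 8.24e-05, and adjusted p = 0.314 with an estimated correlation). All 37 measured replication and mitosis genes were lower, with a median of -0.48 (adjusted p = 0.00195, and adjusted p = 0.79 with an estimated correlation). Camera called 16 lists in all, none with an estimated correlation, and another split of the same 6 mice gave 22.

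The comparison of MIX with HD addresses estradiol on the high-fat diet, and 3 features passed. Bmp5 fell from 6.30 ± 0.06 in HD to 4.31 ± 0.21 in MIX, which is below the array medians. The difference adjusted for code style was -2.25 (SE 0.18, adjusted p = 0.0095 in limma), with a range of -2.514 to -1.93 over the alternatives. Alas2 rose from 7.46 ± 0.96 to 8.53 ± 0.22 (1.89, SE 0.18, adjusted p = 0.0265), with a range of 0.864 to 2.017 over the alternatives, past the threshold in 10 of 21. Mean hemoglobin was 11.06 and 11.13 in HD replicates 1 and 2, close to the 11.19 to 11.32 in MIX. Only HD replicate 3, the lettered HD mouse, was far lower, at 8.37. Trp63 rose from 4.43 ± 0.07, below the array medians, to 5.28 ± 0.10 (0.84, SE 0.08, adjusted p = 0.0265 in limma), with a range of 0.786 to 0.942 over the alternatives. Values that missed the threshold included Olfm4 (5.27, SE 0.58, adjusted p = 0.0519), Krt13, a keratin of stratified mucosa (3.45, SE 0.44), Krt15 (2.50, SE 0.31), the corepressor gene Tle4 (1.13, SE 0.14), the vitamin D receptor gene Vdr (0.94, SE 0.13), Tanc2 (0.66, SE 0.09) and Hba-ps4 (1.48, SE 0.19). Each of the 3 MIX mice lay outside the range of the 3 HD mice for all 10 of these genes.

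In MIX against HD 4649 features had an unadjusted p under 0.05, and 15.9% of features showed no overlap between the groups, where chance gives 10%. Squamous markers had a median of 0.87 with 12 members past the threshold adjusted over the list alone and 1, Trp63, over all features (adjusted p = 6.14e-20, and adjusted p = 0.304 with an estimated correlation). Cytokine and chemokine genes had a median of 0.76, with Il33 at 2.52 (SE 0.48) and Cxcl5 at 3.29 (SE 1.03; adjusted p = 6.51e-10, and adjusted p = 0.304 with an estimated correlation), and a score difference of 0.912 that was 0.464 without MIX replicate 3. Of the antigen presentation genes 19 of 19 were higher, H2-Ab1 by 1.51 (SE 0.41) and H2-DMb1 by 1.49 (SE 0.41; adjusted p = 2.33e-08, and adjusted p = 0.304 with an estimated correlation). Camera called 20 lists, all higher in MIX, and 0 with an estimated correlation, though stromal markers went from 0.425 to 0.02 and endothelial ones from 0.388 to 0.032 without MIX replicate 2, and another split of these 6 mice gave 21. The count of 3 features was 0 without HD replicate 1 or CON replicate 3, 1 without CON replicate 1 or 2 or E2 replicate 1 or 2, 5 without E2 replicate 4, 80 without MIX replicate 1 and 53 without MIX replicate 2.

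The comparison of MIX with E2 addresses the high-fat diet in mice that carry a pellet. Alas2 (1.62, SE 0.18, adjusted p = 0.196) and Trp63 (0.69, SE 0.08, adjusted p = 0.227) had the smallest p, followed by Bmp5 (-1.20, SE 0.18). The Alas2 means were 7.83 in E2 and 8.53 in MIX, a difference of 0.698 without the code style term, and the gene follows hemoglobin. Akr1c21, which encodes a hydroxysteroid dehydrogenase, was at 6.56 ± 1.48 in MIX and at background, 3.16 ± 0.15, in E2, so no exact difference is given. Krt15 (1.669, SE 0.30), Tle4 (0.81, SE 0.14), Vdr (0.75, SE 0.13), Hspa2 (0.53, SE 0.10), Hba-ps4 (1.17, SE 0.19) and Hmga2, a chromatin protein gene (-0.88, SE 0.17), completed the 10. Limma called 0 features, with 1832 at an unadjusted p under 0.05. Simulated data recovered 71% of 100 features given a log2 difference of 1 here and 92% of 100 given 2. The count became 24 without MIX replicate 2 and 2 without MIX replicate 3.

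Squamous markers again had the smallest camera p between MIX and E2, with a median of 0.73, 27 of 28 members higher and 8 past the threshold adjusted over the list alone against 0 over all features (adjusted p = 3.94e-20, and adjusted p = 0.471 with an estimated correlation). Interferon-stimulated genes had a median of -0.90 with 27 of 30 members lower, Mx2 (-1.57, SE 0.50) and Irf9 (-0.37, SE 0.13) among them (adjusted p = 5.06e-13, and adjusted p = 0.668 with an estimated correlation). E2 replicate 4, the only lettered E2 mouse, had the highest interferon score of all mice, 9.37 where the other E2 mice had 7.49 to 8.10. The score difference, which has no code style term, was -0.313 (exact p = 0.714) and turned to 0.096 without that mouse. It was -0.531 without E2 replicate 2, -0.491 without E2 replicate 3, -0.116 without MIX replicate 2 and -0.5 without MIX replicate 3. Fatty acid oxidation genes had a median of 0.13, with Pdk4 at 1.01 (SE 0.39) and Slc25a20 at 0.40 (SE 0.15; adjusted p = 8.53e-05, and adjusted p = 0.387 with an estimated correlation). Replication and mitosis genes had a median of -0.48, with Cdc6 at -1.05 (SE 0.54; adjusted p = 1.59e-05, and adjusted p = 0.771 with an estimated correlation), and a score difference of -0.821 that was -1.27 without E2 replicate 2. Of 14 called lists none held with an estimated correlation.

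The interaction asks whether the pellet difference depends on the diet. The smallest p belonged to Trp63 and Bmp5, both near background in at least 1 group and so given no value, then Alas2 (1.33, SE 0.24, or 0.403 without the code style term), Creb3l4 (0.55, SE 0.11), Tle4 (0.93, SE 0.18), Vdr (0.75, SE 0.17), Klf10 (0.99, SE 0.22), Akr1c21 (at background outside MIX and given no value), Zfp605 (-0.68, SE 0.16) and Krt15 (1.666, SE 0.40). Each had an adjusted p of 1, and limma called 0 features, with 1382 at an unadjusted p under 0.05. Without MIX replicate 2 it called 2. Whether the pellet difference of the basal markers Trp63 and Krt15 depends on the diet is thus not shown.

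Across all 65929 features, and without the code style term, the pellet differences on the 2 diets correlated with Pearson's r = 0.469 (Spearman's rho = 0.271), and the diet differences without and with a pellet with r = -0.00183 (rho = -0.00792). Features are not independent replicates, so no p is given. The pairs share no mouse, but that does not make them independent. E2 replicate 1 and MIX replicate 3, which enter 1 pellet difference each, departed from their group means alike across features (r = 0.485). That was the highest value for any 2 mice of different groups. The agreement was not computed without these 2 mice, so a structure they share apart from the pellet may add to it.

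The pellet differences were averaged over both diets in a comparison added after the planned ones had given few passing features. Olfm4 rose with the pellet by 4.29 (SE 0.37, 19.5-fold, adjusted p = 0.00989), from 4.94 and 4.96 in CON and HD to 8.30 and 9.78 in E2 and MIX, and was higher in all 7 mice with a pellet than in any of 6 without. The keratins of stratified epithelium Krt13 (2.54, SE 0.28, adjusted p = 0.0296) and Krt15 (1.665, SE 0.19, adjusted p = 0.04) and the scaffold gene Tanc2 (0.53, SE 0.05, adjusted p = 0.0279) rose with the same full separation. Bmp5 fell by 1.47 (SE 0.11, adjusted p = 0.00727), Hs3st3b1 fell by 0.68 (SE 0.08, adjusted p = 0.0296) and Cdh4 fell by 0.85 (SE 0.10, adjusted p = 0.0453), and Alas2 rose by 1.23 (SE 0.11, adjusted p = 0.0148). Bmp5, Cdh4 and Alas2 overlapped between mice with and without a pellet.

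**Figure D1:**
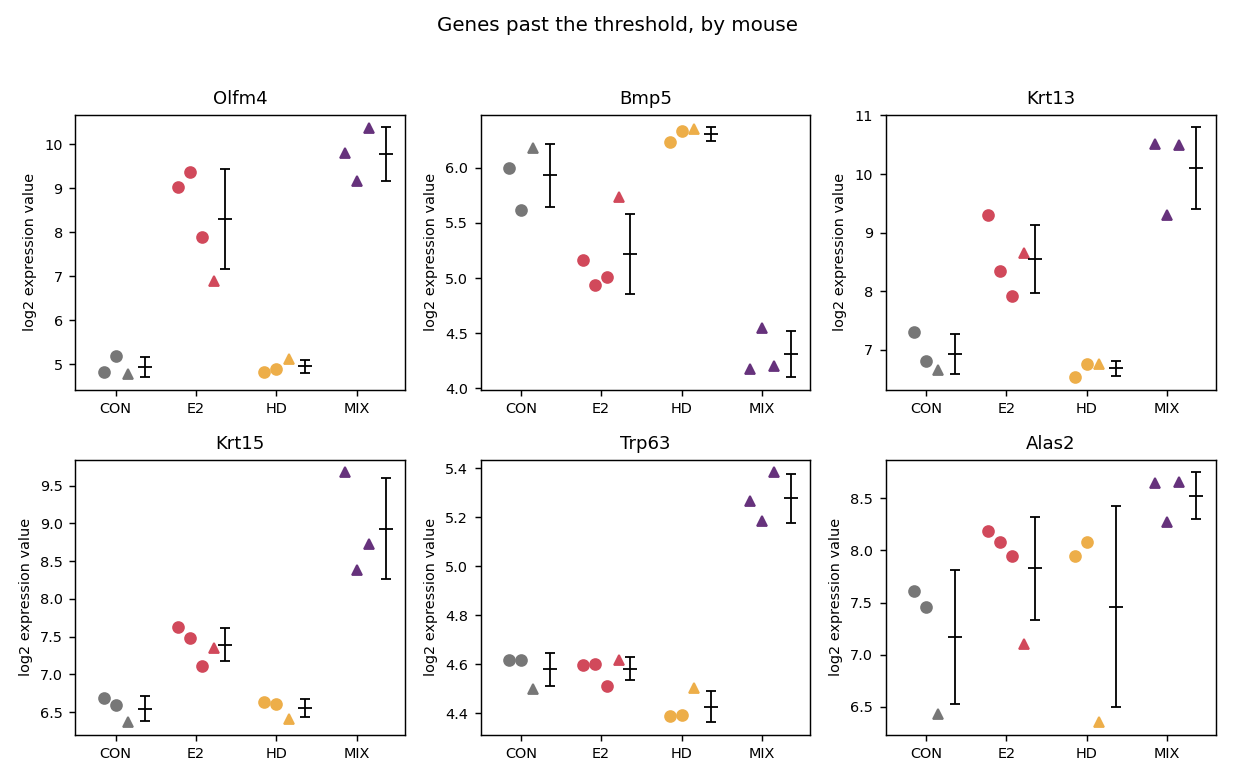
Log2 expression of 6 genes in each mouse, by group on the horizontal axis; round points are mice with numbered codes, triangles mice with lettered codes, and black bars the group mean ± SD. Olfm4 was between 4.94 and 4.96 on average without a pellet and 8.30 and 9.78 with one, and Trp63 averaged 4.43 to 4.58 in CON, E2 and HD and 5.28 in MIX.

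Limma called 7 features up and 4 down for the averaged pellet difference, with 6584 at an unadjusted p under 0.05 where chance gives 3296. The remaining 3 called features were the predicted gene Gm13453 (0.57, SE 0.06), and the unnamed features TC0100003627.mm.1 (1.15, SE 0.13) and TC0200000706.mm.1 (-0.74, SE 0.09), named here after their values were seen. Ltf (0.39, SE 0.18), Lcn2 (0.17, SE 0.16), Pgr (-0.55, SE 0.31) and Esr1 (-0.46, SE 0.19) did not pass, nor did Trp63 (0.42, SE 0.05, adjusted p = 0.0511) and Hba-ps4 (0.99, SE 0.12, adjusted p = 0.0511). Full separation was seen for 342 features, 0.519% of all, where chance gives 0.117%. The count of 11 was 2 without CON replicate 1, 1 without CON replicate 2, 0 without CON replicate 3, 3 without E2 replicate 1, 5 without E2 replicate 2, 6 without E2 replicate 4, 1 without HD replicate 1, 3 without HD replicate 2 and 2 without HD replicate 3. It was 224 without MIX replicate 1, 54 without MIX replicate 2, 7 without MIX replicate 3, and 0 without both E2 replicate 1 and MIX replicate 3. Simulated data recovered 84% of 100 features given a log2 difference of 1 and 99% of 100 given 2.

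With the mouse as the unit, the scores of 10 lists rose with the pellet past the threshold of an exact permutation test over 700 relabelings. Cytokine and chemokine genes rose by 0.99 (exact p = 0.00143, the smallest possible, adjusted p = 0.0245), granulocyte markers by 1.00 (exact p = 0.00429, adjusted p = 0.0245; 0.646 without MIX replicate 3 and 0.51 without it and E2 replicate 1), macrophage markers by 0.94 (exact p = 0.00286, adjusted p = 0.0245) and complement and mucosal defence genes by 0.74 (exact p = 0.00143, adjusted p = 0.0245). Squamous markers rose by 0.81 (exact p = 0.00429, adjusted p = 0.0245), mesothelial markers by 0.69 (exact p = 0.00286, adjusted p = 0.0245) and uterine estradiol targets by 0.45 (exact p = 0.00429, adjusted p = 0.0245). Antigen presentation genes rose by 0.48 (exact p = 0.01, adjusted p = 0.04), lymphocyte markers by 0.34 (exact p = 0.00714, adjusted p = 0.0317) and protein folding stress genes by 0.23 (exact p = 0.00571, adjusted p = 0.0286).

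Single members show what these lists held. S100a8, a calcium-binding protein of granulocytes, was below the array medians at 3.28 in CON and 4.21 in HD, and at 7.59 in E2 and 8.43 in MIX, and S100a9 differed by 3.81 (SE 0.86). Il33 differed by 1.85 (SE 0.31), Csf1 by 0.99 (SE 0.19), C4b by 1.18 (SE 0.22), H2-Ab1 by 1.23 (SE 0.26), the mesothelial Muc16 and Bnc1 by 0.97 (SE 0.17) and 0.97 (SE 0.18), Cd3g by 0.72 (SE 0.19) and Herpud1 by 0.66 (SE 0.18). Adjusted over the list alone, 19 macrophage markers were higher and 1 lower, and 14 cytokine, 13 defence, 13 squamous, 9 mesothelial, 8 antigen presentation, 6 estradiol target, 6 protein folding, 2 granulocyte (S100a8 and S100a9) and 0 lymphocyte genes were higher. Over all features the passing members were Olfm4, Krt13 and Krt15. The 10 lists are not wholly separate results. Also in other lists were 10 of 37 estradiol targets, 7 of 32 defence genes and 5 of 24 granulocyte markers, against 0 of 28 squamous and 0 of 19 antigen presentation genes. S100a8 and S100a9 are in the defence list as well. Of the 24 granulocyte markers, 12 lay above the array median in every CON mouse.

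**Figure D2:**
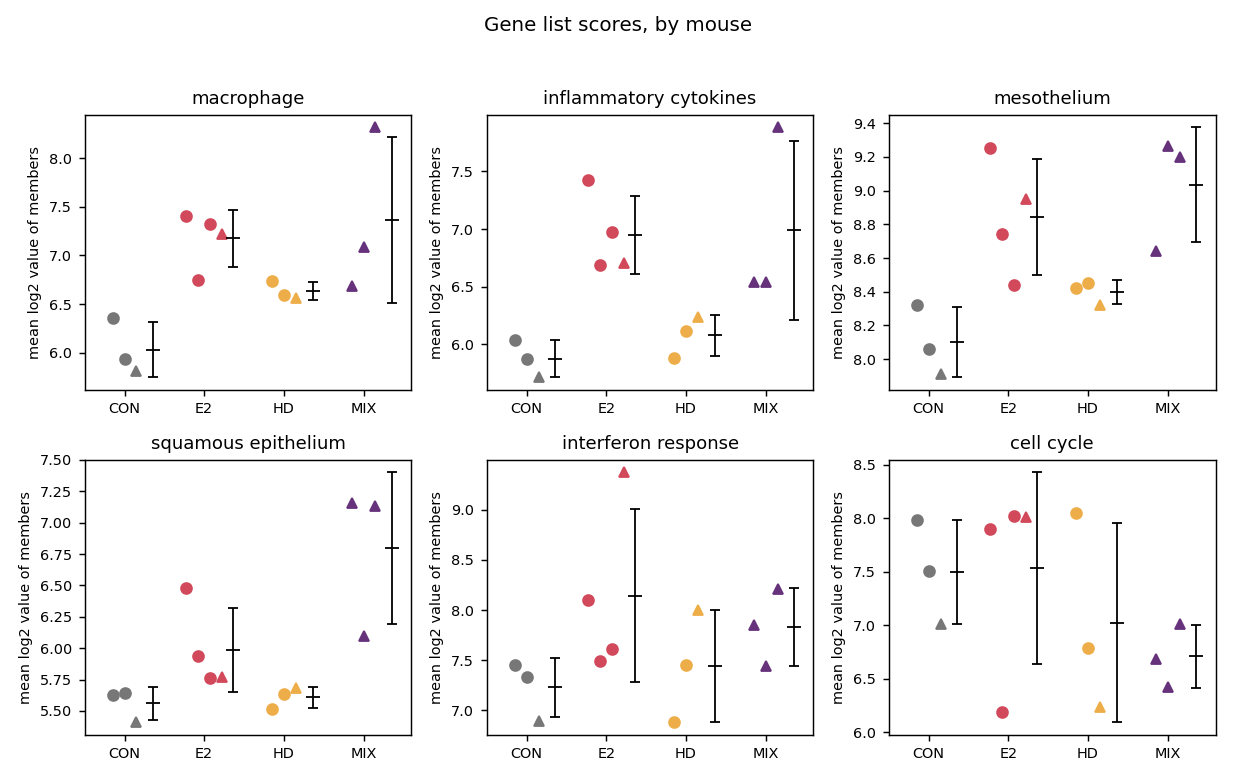
Mean log2 value of the members of 6 gene lists in each mouse, by group; round points are mice with numbered codes, triangles mice with lettered codes, and black bars the group mean ± SD. Macrophage scores averaged 6.03 in CON and 6.63 in HD against 7.18 in E2 and 7.36 in MIX, and the squamous score was highest in MIX, at 6.79 ± 0.61.

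These list scores moved with other features of the samples. The mean of the 4 hemoglobin features was also higher with the pellet, by 0.88 (exact p = 0.031), and MIX replicate 3 had the highest macrophage score of all mice, 8.32. Within code style all 10 lists had an exact p of 0.0125 to 0.0375, where 80 relabelings are possible and 0 lists pass after adjustment. Without E2 replicate 1 and MIX replicate 3 the 10 exact p were 0.005 to 0.03, again with 0 lists passing after adjustment over 200 relabelings. The count of 10 was 6 without CON replicate 2 or E2 replicate 4, 5 without E2 replicate 1, and 0 without CON replicate 3 or any 1 HD mouse. Before adjustment, all 10 lists kept their direction and an exact p under 0.05 without CON replicate 3 or HD replicate 2 or 3. Without HD replicate 1, 9 did.

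By camera, 20 lists were called for the averaged pellet difference and 0 with an estimated correlation, the lowest adjusted p being 0.227 with an estimated correlation. Hypoxia and glycolysis genes, with a score difference of 0.48 (exact p = 0.0257, adjusted p = 0.0857), cholesterol efflux genes, with 0.32 (exact p = 0.02, adjusted p = 0.0727), and interferon-stimulated genes, with 0.65 (exact p = 0.0629, adjusted p = 0.14), did not pass per mouse.

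The diet difference averaged over both pellet states was added at the same time. Alas2 had the smallest p (0.96, SE 0.12, adjusted p = 0.595; 0.496 without the code style term), followed by Rap2a (0.35, SE 0.06), Hba-ps4 (0.68, SE 0.13), the forkhead gene Foxi3 (-0.60, SE 0.12), Scarb2 (0.36, SE 0.07), Hspa2 (0.32, SE 0.06), the histone gene H1f2 (0.65, SE 0.13), Trp63 (0.27, SE 0.06), Hmga2 (-0.55, SE 0.12) and the arginine methyltransferase gene Prmt5 (-0.39, SE 0.08). Limma called 0 features, with 2217 at an unadjusted p under 0.05, and 22 features separated the 6 mice on the diet from the 7 others, 0.0334% where chance gives 0.117%. Simulated data recovered 89% of 100 features given a log2 difference of 1 and 99% of 100 given 2.

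No list passed for the diet per mouse. Heat shock genes had the smallest p, with a score lower by 0.24 on the diet (difference -0.242, exact p = 0.00286, adjusted p = 0.114), and Hspb1 (-0.42, SE 0.17) and Hspd1 (-0.27, SE 0.13) as members. Replication and mitosis genes had the largest difference, -0.648 (exact p = 0.126, adjusted p = 0.657), with group scores of 7.501 ± 0.49 in CON, 7.53 ± 0.90 in E2, 7.03 ± 0.93 in HD and 6.71 ± 0.30 in MIX. Squamous markers differed by 0.43 (exact p = 0.0614, adjusted p = 0.657) and macrophage markers by 0.39 (exact p = 0.131, adjusted p = 0.657), or 0.154 without MIX replicate 3. Among the lipid lists, fatty acid oxidation differed by 0.08 (exact p = 0.111; 0.053 without MIX replicate 2), lipogenesis by -0.03 (exact p = 0.513; -0.042 without E2 replicate 3 to -0.005 without E2 replicate 4) and cholesterol synthesis by -0.05 (exact p = 0.787; -0.135 without MIX replicate 3 to 0.071 without MIX replicate 2, so it has no settled direction), with Scd1 at -0.95 (SE 0.26). Camera called 13 lists and 0 with an estimated correlation, the lowest adjusted p being 0.707 with an estimated correlation.

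**Figure D3:**
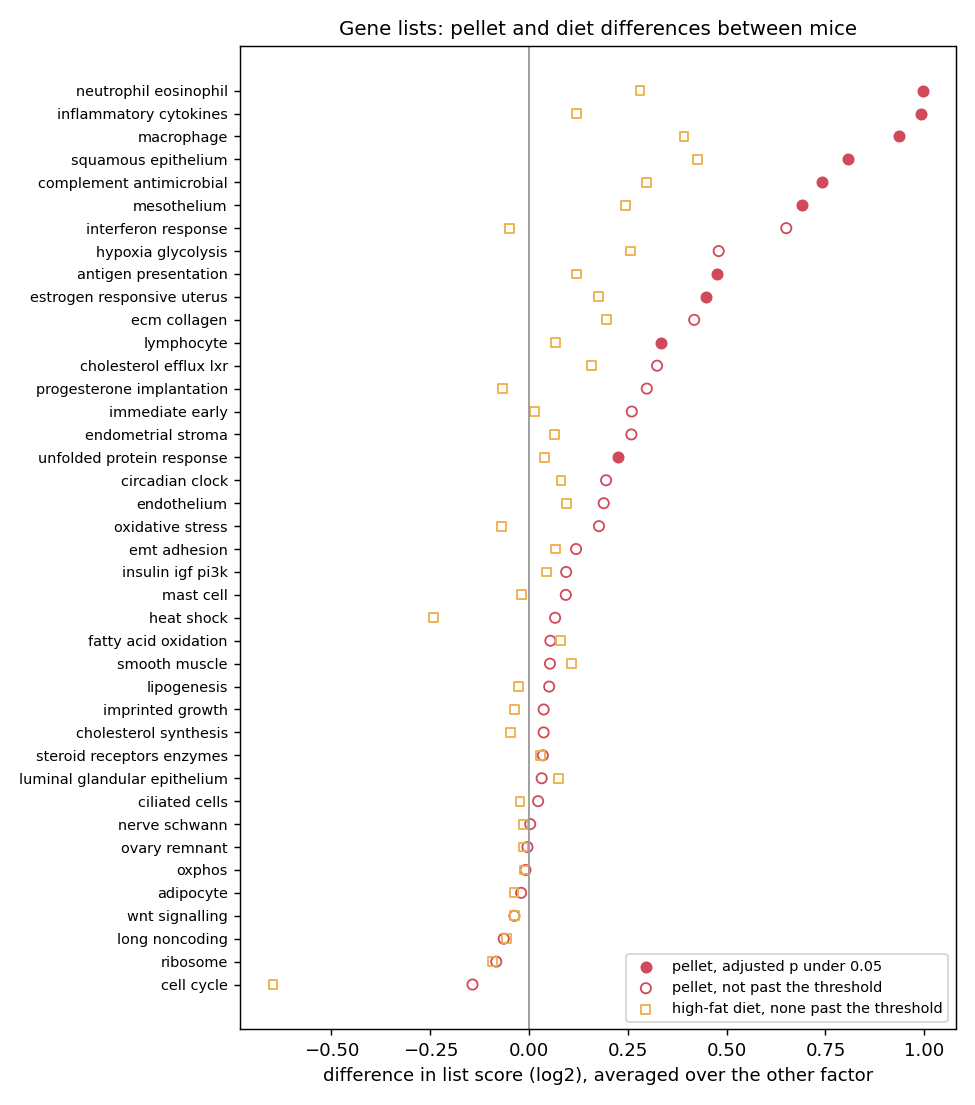
Difference in list score (log2) for 40 gene lists, with the pellet difference averaged over diets as circles and the diet difference averaged over pellet states as squares; filled circles are the 10 lists past an adjusted p of 0.05. The pellet differences ran from -0.143 for replication and mitosis genes to 0.997 for granulocyte markers, and no diet difference passed. For replication and mitosis genes the pellet difference changes sign without HD replicate 1, so it has no settled direction.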

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

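The tests of single explanations below were chosen after the results they address had been seen, except the one of blood for the macrophage markers and the counts over other splits of the mice.

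Among 80 series of values in the 4 E2 mice (list scores and named genes), 5 had 1 mouse far from the other 3, about as many as chance gives at 1 in 20. The score of replication and mitosis genes was 6.19 in E2 replicate 2 and 7.90 to 8.02 in the others. That of adhesion and mesenchymal genes was 8.17 in E2 replicate 3 and 8.33 to 8.36 in the others, and that of imprinted growth genes 5.92 in E2 replicate 1 and 6.02 in each of the others. In E2 replicate 4, Ccnd2 was at 8.89 where the others had 7.62 to 7.82, and Zfp362 at 7.87 where they had 7.40 to 7.46.

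Camera called 12 of 40 lists for the interaction at its preset correlation and 0 with an estimated one, so a dependence of the pellet difference on the diet is not shown. The median interaction was 0.725 for squamous markers, 0.352 for endothelial, 0.254 for matrix, 0.229 for smooth muscle, 0.223 for adhesion and mesenchymal, 0.195 for lymphocyte, 0.194 for clock, 0.159 for oxidative stress, 0.128 for insulin signalling and 0.089 for fatty acid oxidation genes. It was -1.135 for interferon-stimulated and -0.142 for respiratory chain genes. The lowest adjusted p was 0.462 with an estimated correlation. Other splits of the mice gave as many as 23 called lists where the real one gave 12, and 67 of 100 gave at least as many, so chance cannot be excluded. In list scores, which have no code style term, the interaction rested on single mice for 6 of these lists. For interferon-stimulated genes it was -0.529, but -0.119 without E2 replicate 4, -0.251 without HD replicate 3, -0.332 without MIX replicate 2 and -0.811 without HD replicate 1. For endothelial markers 0.4 became 0.043 without MIX replicate 2 and 0.712 without MIX replicate 1, for smooth muscle 0.39 became 0.238 and 0.651, and for lymphocytes 0.32 became 0.208 and 0.506. For insulin signalling 0.135 became 0.036 without MIX replicate 2 and 0.081 without E2 replicate 3. For matrix genes 0.145 turned to -0.108 without MIX replicate 3, and was 0.017 without CON replicate 1, 0.093 without CON replicate 2, 0.22 without E2 replicate 1, 0.022 without E2 replicate 3, 0.326 without CON replicate 3 and 0.416 without MIX replicate 1.

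Macrophage markers were higher with the pellet by 0.94. Without E2 replicate 1 and MIX replicate 3, the mice farthest along the first principal component, the difference was 0.66 (exact p = 0.015). This argues against these 2 mice as the whole cause of the difference averaged over diets. On chow the other E2 mice had scores of 6.751 to 7.326, above the 5.808 to 6.353 of CON. On the high-fat diet MIX replicates 1 and 2 had 6.683 and 7.087, where HD mice had 6.567 to 6.735. There the rise thus rested largely on MIX replicate 3, at 8.316. A smaller share of epithelium would raise the markers of other cell types alike, but stroma, smooth muscle, endothelium and nerve scores differed by 0.126 on average and macrophage scores minus their mean by 0.811 (exact p = 0.0171). Mesothelial (0.691, exact p = 0.00286), lymphocyte (0.335, exact p = 0.00714) and matrix scores (0.418, exact p = 0.0457) were higher too, so the markers moved apart. The score of uterine epithelial markers itself differed by -0.065 between E2 and CON and by 0.107 between MIX and CON. These values argue against a smaller share of epithelium as the whole cause and leave a part of it open, since the score was slightly lower in E2. With the hemoglobin features as a covariate the difference was 0.906 (permutation p = 0.02), and with their square as well it was 0.853 (permutation p = 0.043). Both argue against blood as the whole cause, the second narrowly. A larger share of macrophages, or higher expression of these genes in other cells, may account for the rest: 24 of the 32 markers lay above the array median in every CON mouse and 1 is in another list.

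Squamous epithelial markers were higher with the pellet by 0.81. Without MIX replicate 3 the difference was 0.723 (exact p = 0.00286), and with relabelings within code style the exact p was 0.0125, which argues against this mouse and against code style as the whole cause. MIX replicate 1 had the highest squamous score, 7.157, next to 7.132 in MIX replicate 3. Over fits without each mouse in turn the difference was 0.717 to 0.982, with an exact p of at most 0.0314. Cervical or vaginal epithelium carried into the scraping is a candidate source. The regional genes Hoxa13 and Hoxd13 differed by -0.022 with the pellet, with a 95% interval up to 0.058, at mean levels of 5.54 and 3.27, the second below every array median. Their levels in cervix and vagina were not measured here, so the rise that a small share would bring is not known, and such tissue and a squamous change of the endometrium itself cannot be told apart. Of the 28 markers, 20 lay above the array median in every CON mouse and 0 are in other lists. Basal genes (Krt5, Krt14, Krt15, Trp63, Dsc3, Dsg3), a set chosen after the result, differed by 1.45 (exact p = 0.00286) and cornified ones by 0.198 (exact p = 0.276). The cornified set averaged 5.81, 4.77 and 5.11 in MIX replicates 1 to 3 and 4.81 to 4.92 in all other mice. These levels are close to the array medians, where differences are compressed, so a change of basal genes alone is not shown.

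Alas2 was higher in MIX than in CON mice by 2.18 (95% interval 1.738 to 2.628), and the mean of the 4 hemoglobin features by 2.077 (1.149 to 3.006). Both values rest on the code style term: hemoglobin itself was 11.19 to 11.32 in MIX and 9.31 to 10.80 in CON mice, and Alas2 differed by 1.361 without that term. Over the 13 mice Alas2 and hemoglobin correlated with Pearson's r = 0.931 (n = 13, permutation p = 1e-05, the smallest the permutations can give; Spearman's rho = 0.977, and r = 0.972 without the 2 farthest mice, HD replicate 3 and CON replicate 3), the 1 relation tested. With hemoglobin as a straight covariate the Alas2 difference was 1.37 (0.785 to 1.955); a squared term, added after that result was seen, brought it to -0.386 (-1.331 to 0.558). Blood in the scraping and a change in Alas2 itself therefore cannot be told apart, since the answer depends on the shape assumed for the relation. Lettered mice had lower Alas2 than numbered ones of the same group, by a coefficient of -1.234 with a 95% interval up to -0.906, so code style runs against the difference.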

How the results depend on the processing

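The averaged comparisons, the tests per mouse and the fits without both E2 replicate 1 and MIX replicate 3 were chosen after the data had been seen. So were the camera calls without each mouse in turn. The other alternatives were planned. Limma called 0 features for E2 with CON and for HD with CON under each alternative tried, where 2651 and 1918 had an unadjusted p under 0.05.

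Without the code style term the counts were 15 for MIX with CON, 12 for MIX with HD and 1 for MIX with E2, and with code style as a random block 27, 15 and 1. The correlation within a style was estimated at -0.0497 from only 2 styles. The random block counts are therefore not adjusted for code style as those of the main fit are. With a block by replicate number, which does not pair the mice here, they were 0 for MIX with CON, MIX with HD and the averaged pellet difference. Quantile normalization again gave 1 for MIX with CON and 5 for MIX with HD, and median centring 5 for MIX with CON. Leaving out dim features gave 11 and 5, features with 1 symbol 13, 7 and, for the pellet, 17, and both test fewer features. Array weights gave 13 for MIX with CON, 7 for MIX with HD and 1 for the diet. Only the 2 groups gave 0 for MIX with CON and for MIX with HD, with fewer mice in the fit. Only lettered mice gave 0 for both as well, but CON and HD then have 1 mouse each, so this says little. For the pellet the trend and robust options gave 7 and a minimum log2 difference of 1 gave 6. Without both E2 replicate 1 and MIX replicate 3 the counts were 0 for the pellet, 1 for the diet and 1 for MIX with E2. Where no reason is given, the cause was not tested.

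Leaving out 1 mouse at a time, where a lone lettered mouse is assumed to vary like the others, gave 0 to 89 features for MIX with CON, 0 to 24 for MIX with E2, 0 to 80 for MIX with HD, 0 to 2 for the interaction, 0 to 224 for the pellet and 0 to 3 for the diet (3 without HD replicate 3, 1 without MIX replicate 2 or 3). Lists called by camera numbered 0 with an estimated correlation in all 8 comparisons. Without 1 mouse they numbered 9 to 22 for E2 with CON, 4 to 12 for HD with CON, 11 to 23 for MIX with CON, 8 to 21 for MIX with E2, 18 to 25 for MIX with HD, 8 to 15 for the interaction, 15 to 21 for the pellet and 5 to 20 for the diet. Without CON replicate 3 they were 9, 4, 8 and 5 for E2 with CON, HD with CON, MIX with E2 and the diet. Lists past the threshold per mouse for the pellet numbered 0 within code style, 0 without both mice and 0 to 14 without 1 mouse. With code style in the fit the diet differences without and with a pellet correlated with r = 0.131.

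The 13 gene calls kept their direction under all 273 alternative values and passed in 153 of them. Olfm4 ranged from 4.01 to 4.64 for the pellet (past in 17 of 21), Bmp5 from -1.60 to -1.33 (19 of 21), Trp63 in MIX against HD from 0.79 to 0.94 (9 of 21), Alas2 from 1.16 to 2.31 in MIX against CON (12 of 21), 0.86 to 2.02 in MIX against HD (10 of 21) and 0.78 to 1.29 for the pellet (12 of 21), and Bmp5 from -2.06 to -1.56 in MIX against CON (10 of 21) and -2.51 to -1.93 in MIX against HD (18 of 21). For the pellet Krt13 ranged from 2.28 to 2.74 (10 of 21), Krt15 from 1.48 to 1.81 (10 of 21), Tanc2 from 0.50 to 0.59 (12 of 21), Hs3st3b1 from -0.72 to -0.59 (8 of 21) and Cdh4 from -0.90 to -0.67 (6 of 21). The 99 gene values that had not passed gave 2079 alternative values, of which 89 passed and 31 had the other sign. RMA compresses dim signals, and 34615 features lay above the limit used for dim ones.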

Other observations

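The counts over other splits of the mice were chosen before the results they address, and those for the 2 averaged comparisons were added with those comparisons.

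For each comparison the mice were also split in other ways into groups of the same sizes, and the same fit was made. For E2 with CON the real count was 0 features and the highest of the other splits 0, so 35 of 35 splits gave as many, and for called lists 17 against a highest other of 19, with 7 of 35 splits at least as high. For MIX with E2 it was 0 features against 102, with 35 of 35 as high, and 14 lists against 22, with 24 of 35 as high. Chance cannot be excluded for these lists. Groups of 3 against 3 allow 10 splits, too few for a share under 0.05. There the real and highest other values were 0 and 0 features (10 splits as high) and 8 and 15 lists (4 as high) for HD with CON, 2 and 2 features (2 as high) and 16 and 22 lists (5 as high) for MIX with CON, and 3 and 56 features (2 as high) and 20 and 21 lists (2 as high) for MIX with HD.

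For the pellet difference averaged over diets, 100 of the 700 possible splits were drawn, the real one among them. At least the real count of 11 features came from 2 of these, the real split and another with 30, a share under 0.05 in this draw. Of 700 relabelings, 1, the real one, gave as many lists past the threshold per mouse, 10 where the highest other gave 9, a share under 0.05 as well. Neither share allows for the choice of this comparison and test after the planned ones had been seen, and without CON replicate 3 both counts are 0. Both shares therefore hold only for the comparison as run. For lists called by camera chance cannot be excluded: 19 of 100 splits gave at least the real 20, and the highest other gave 24. For the averaged diet difference the real value was 0 features against 127 (100 of 100 splits as high), 13 called lists against 24 (67 of 100) and 0 lists per mouse against 4 (700 of 700), and for the interaction 0 features against 204 (100 of 100).

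The highest counts of other splits, where the median of the other splits was 0, point to a structure of the samples other than the groups, which was not tested further. The split with 102 features in MIX with E2 set E2 replicate 1, MIX replicate 1 and MIX replicate 3 against the rest, and the one with 56 in MIX with HD set HD replicate 3, MIX replicate 1 and MIX replicate 3 against the rest. In the latter all 3 mice on 1 side carry lettered codes and 1 of 3 on the other, as in the real split.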
